A study of Mus musculus with 8 samples.

How the data were processed

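The samples are RNA from mouse eyes, hybridized to 8 Affymetrix mouse expression arrays, per the labels. The titles name 2 kinds of eye, KPAW and wild type, at 2 ages, 5 days and 1 month, with 2 arrays numbered I and II in each of the 4 groups. KPAW is not expanded in the labels. The 5-day wild type is given as C57Bl6 per the labels, and the strain of the other groups is not given. Total RNA was prepared with Trizol and cleaned on RNeasy columns, per the labels' protocols. Neither the labels nor the numerals say whether the arrays of a group are separate animals. Every p-value for a single probe set thus measures only the spread between these arrays. The p-values for gene lists set the genes of a list against all other genes, and the permutation p rests on random draws of genes. Neither kind gives the spread between animals.

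The deposited values are 1 signal per probe set and array, per the file headers. The software that made them is not given in the sources used here. Each array's control probe sets had a median of 1, no value lay below 0.01, and 10.0% to 14.9% of the probe sets of an array were listed at that lowest value. The rule set in advance for recognising linear values expected a much larger maximum than the 11.1 found here. The values were treated as linear signals all the same, because they held a fixed lowest value, no negative values and a long upper tail. Depth has no meaning for arrays, whose number limits the precision.

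Of 22690 probe sets, 64 controls were left out. Among the other 22626, 20380 carried 1 gene symbol, 691 carried several and 1555 carried none, and the single symbols named 12393 genes. Trimmed means (2% off each end) ran from 0.144 to 0.256, a ratio of 1.77, so each array was scaled to the median of the 8 trimmed means. Values were then taken as log2(signal + 0.0211), the pseudocount being the 20th percentile of all positive values. Probe sets whose mean signal lay above the 30th percentile were kept, which left 15838 probe sets and 9492 genes. Each gene was represented by its single-symbol probe set with the highest mean signal. All columns of the table were used.

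A single limma model with a mean for each of the 4 groups was fitted to all 8 arrays, with 4 residual degrees of freedom and a variance trend (limma 3.58.1, R 4.3.3). The contrasts were KPAW against wild type at each age, the change in that difference between the ages, and 1 month against 5 days in each kind of eye. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over the probe sets kept, separately for each contrast. Log2 fold changes are given with the standard error of the model, and signals are scaled signals given as mean ± SD over the 2 arrays of a group. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

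Before the data were examined, 46 gene lists with 1053 genes were written from textbook knowledge of the tissues of the eye, its surroundings and common cell programs, and 902 of these genes were on the array. Some genes fixed in advance had no probe set of their own in the table used here. Lists were tested with camera in limma, a two-sided test of a list against all other genes, with a preset correlation of 0.01 between genes and again with an estimated correlation. The test with an estimated correlation rests on the 4 residual degrees of freedom. It called no list in any contrast, even for age in wild type, where most cell cycle genes passed singly. A list that did not pass it is thus not shown to be unchanged. List members were counted past the threshold over all probe sets and also adjusted over the list alone. The genes named were fixed by a rule: for KPAW against wild type all called genes with separate groups, filled up with the largest moderated statistics to 10 in each direction; for the age contrasts the 10 largest called changes in each direction; for the interaction 5 in each direction; for each list up to 4 members with the largest changes; and always Pax6, Krt12, Aldh3a1, Cryaa and the sex-linked genes Xist and Eif2s3y.

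Alternatives were quantile normalization, median scaling, other pseudocounts and filters, no variance trend, a fit of the contrast's groups alone, a replicate block, 1 probe set per gene, a 2-fold minimum and leaving out each array in turn. The values as deposited, a common floor and array weights were chosen after seeing the data. The model was tested on simulated data for 15838 probe sets, with 50 probe sets changed at each of several folds. For the 1-month contrast it recovered 78% of those changed 2-fold and 100% of those changed 4-fold, 8-fold or 16-fold, and called 13 unchanged probe sets. For age in wild type it recovered 82% and 100%, and called 10. The simulated values were normal and independent, with the spread that the model estimated. They lack the divergence seen between some real replicates, so these rates do not carry over to genes on which replicates diverge. A simulated list of 25 independent genes shifted by 1 log2 unit was called with the preset correlation, and 0 of 46 lists without a shift were. Lists whose genes vary together were not simulated, so this does not give the rate of false calls for such lists.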

Results

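Gene expression was measured on 8 arrays of RNA from KPAW and wild-type mouse eyes at 5 days and 1 month of age, with 2 arrays, I and II, in each of the 4 groups. Each array gave a signal for 22690 probe sets, of which 15838 entered the tests. The replicates of a group correlated across probe sets at 0.964 in wild type at 5 days, 0.946 in KPAW at 5 days, 0.969 in wild type at 1 month and 0.927 in KPAW at 1 month. In that order, 225, 438, 168 and 576 probe sets lay more than 2-fold apart between replicates. The first principal component (58.2% of the variance) separated the ages, from -43.4 to -27.1 at 5 days and from 31.8 to 41.3 at 1 month. On the second (19%), KPAW I at 1 month stood at 49.4 and the other 7 arrays between -23.1 and 13.9.

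Sex-linked transcripts differed between arrays. Xist, the RNA that coats the inactive X chromosome, had a deposited signal of 2.71 and 2.88 in the wild-type arrays and 3.48 in KPAW II at 5 days, and Eif2s3y, a Y-linked gene, was at the lowest listed value of 0.01 there. In KPAW I at 5 days Xist was 0.0708 and Eif2s3y 0.129. At 1 month Xist lay between 0.0548 and 0.115 and Eif2s3y between 0.0882 and 0.191 in all 4 arrays. Sex markers thus differed between the KPAW replicates at 5 days and between the ages in wild type, and were alike in the 4 arrays at 1 month.

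At 1 month the comparison of KPAW with wild type asks which transcripts differ in the young adult eye. Rptn, which encodes repetin, a protein of the cornified envelope of keratinizing epithelium, rose from a scaled signal of 0.0103 ± 0.00448 (SD, n = 2) in wild type to 0.598 ± 0.331 (n = 2) in KPAW, a log2 fold change of 4.20 (SE 0.34, adjusted p = 0.0267). For Rptn, wild type I was at the lowest listed value and both wild-type signals lay below the pseudocount of 0.0211. The size of its fold change thus depends on the floor and the pseudocount. Tmem87a, a transmembrane protein gene, rose from 0.0372 ± 0.00607 to 0.213 ± 0.00306, by 2.01 (SE 0.19, adjusted p = 0.0334). A probe set for H2-D1, a class I histocompatibility molecule, fell from 0.892 ± 0.137 to 0.175 ± 0.00274, a log2 fold change of -2.21 (SE 0.19, adjusted p = 0.0267). A probe set of Ppp1r3c, which encodes a glycogen-targeting subunit of protein phosphatase, fell by 1.5 (SE 0.15, adjusted p = 0.0423). It was chosen after its values were seen, because the count is small. The gene's representative probe set, at -1.42, did not pass (adjusted p = 0.0793) but did without KPAW II at 1 month or either KPAW array of 5 days, with a replicate block and as deposited. In all, 4 of 15838 probe sets passed, 2 higher and 2 lower, and 1097 had an unadjusted p under 0.05 where chance gives 792. With array weights 1 passed (Rptn), and 2 (Rptn and H2-D1) with a pseudocount at the 5th percentile or a filter above the 50th. A replicate block gave 13 calls, the groups of the contrast alone 19 and the values as deposited 99. The Ppp1r3c call was also lost with no filter, with the groups alone and without KPAW II at 5 days. A second probe set of Rptn differed by -0.15 (adjusted p = 0.872), and of the other H2-D1 probe sets 1 read -2.44, 1 was higher in KPAW by 2.33 and 1 was at the lowest listed value in both KPAW arrays, none of them passing. At 5 days the called H2-D1 probe set differed by 0.05 (adjusted p = 1.00). No probe set passed without either wild-type array of either age or without KPAW I at 1 month, while 11 passed without KPAW I at 5 days, 10 without KPAW II at 5 days and 563 without KPAW II at 1 month. There KPAW I was the only KPAW array of that age.

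Behind these genes came others with large values that did not pass. The small proline-rich protein gene Sprr3 (log2 fold change 5.24), the late cornified envelope gene Lce3c (4.25), the gel-forming mucin Muc5ac (4.54), the secreted protease inhibitor Slpi (2.46), the chemokine Cxcl17 (1.35), Teddm3 (1.93), AW112010 (2.09) and Sptssb (1.94) were higher in KPAW, with adjusted p between 0.0793 and 0.176. Egln3, an oxygen-sensing prolyl hydroxylase gene (-1.04), the fast-muscle actinin Actn3 (-1.43), the thiamine transporter Slc19a2 (-0.94), Decr2 (-0.96), Rnf157 (-1.04), Enpp5 (-0.95), the glycogenin gene Gyg (-1.03) and H2-M3 (-0.88) were lower, with adjusted p between 0.135 and 0.378. All 8 of the higher genes, and Egln3, Enpp5 and Decr2, passed without KPAW II at 1 month, and Sprr3 and Slpi also without either KPAW array of 5 days. Pax6, the master regulator of eye development, was 0.916 ± 0.205 in wild type and 0.967 ± 0.0246 in KPAW (n = 2 each), a log2 fold change of 0.09 (SE 0.20, adjusted p = 0.916).

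Keratinization genes were the group with the largest mean difference among the 46 lists at 1 month. The list of epidermis-type keratinization and eyelid skin lay higher in KPAW by a mean of 3.01 over its 25 genes (camera adjusted p = 6.25e-15, and adjusted p = 0.548 with an estimated correlation). None of its members passed over all probe sets, and 16 rose when adjusted over the list alone. In 23 of the 25 both KPAW arrays lay above both wild-type arrays, where chance separates 33.3% of genes in the 2 directions together. Sprr3 (5.24, SE 0.65, with wild type II at the lowest listed value) and Calm4 (5.15, SE 1.16) were among its members. The cornified envelope protein loricrin (Lor) and Krtdap were at the lowest listed value in both wild-type arrays, and read 1.96 and 0.980 (Lor) and 1.96 and 0.712 (Krtdap) in KPAW I and II. The list lay 3.59 above the wild-type mean in KPAW I and 2.43 above it in KPAW II, and kept its call without each of the 8 arrays.

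The list of conjunctiva and goblet cells, 13 genes, lay higher in KPAW at 1 month by a mean of 1.51 (adjusted p = 1.48e-06, and adjusted p = 0.548 with an estimated correlation), by 1.94 in KPAW I and 1.07 in KPAW II. None passed over all probe sets, and 4 rose adjusted over the list alone. The goblet-cell mucin Muc5ac went from 0.0592 ± 0.0516 to 2.01 ± 1.64 (n = 2 each), Muc5b differed by 3.58 (SE 0.59), Agr2, which helps fold mucins, by 2.76 (SE 0.58), and the mucosal keratin Krt13 by 2.07 (SE 0.91). Muc5ac, Muc5b and Agr2 passed over all probe sets without KPAW II at 1 month, and Krt13 without either KPAW array of 5 days.

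The corneal epithelium list as a whole did not pass, with a mean of 0.22 over 24 genes (adjusted p = 0.712). It passed with the groups of the contrast alone (0.22) and as deposited (0.21). No member passed over all probe sets, and 1 was lower adjusted over the list alone. Its members went both ways. Krt12, the keratin of the differentiated cornea, was 7.29 ± 0.741 in wild type and 2.76 ± 3.35 in KPAW (log2 fold change -2.32, SE 0.92, adjusted p = 0.675). The KPAW arrays read 0.391 in I and 5.13 in II, against 6.77 and 7.82 in wild type. Slurp1 (-2.46, SE 0.69), Aldh3a1, an abundant dehydrogenase of the cornea (-0.90, SE 0.45), and the water channel Aqp5 (-0.75, SE 0.27) were lower, while Krt14, the keratin of basal cells, was higher by 2.54 (SE 1.08). None of these passed, but Krt12 (-4.15) and Slurp1 (-3.82) did without KPAW II at 1 month, and both did as deposited (-2.60 and -2.74).

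**Figure D1:**
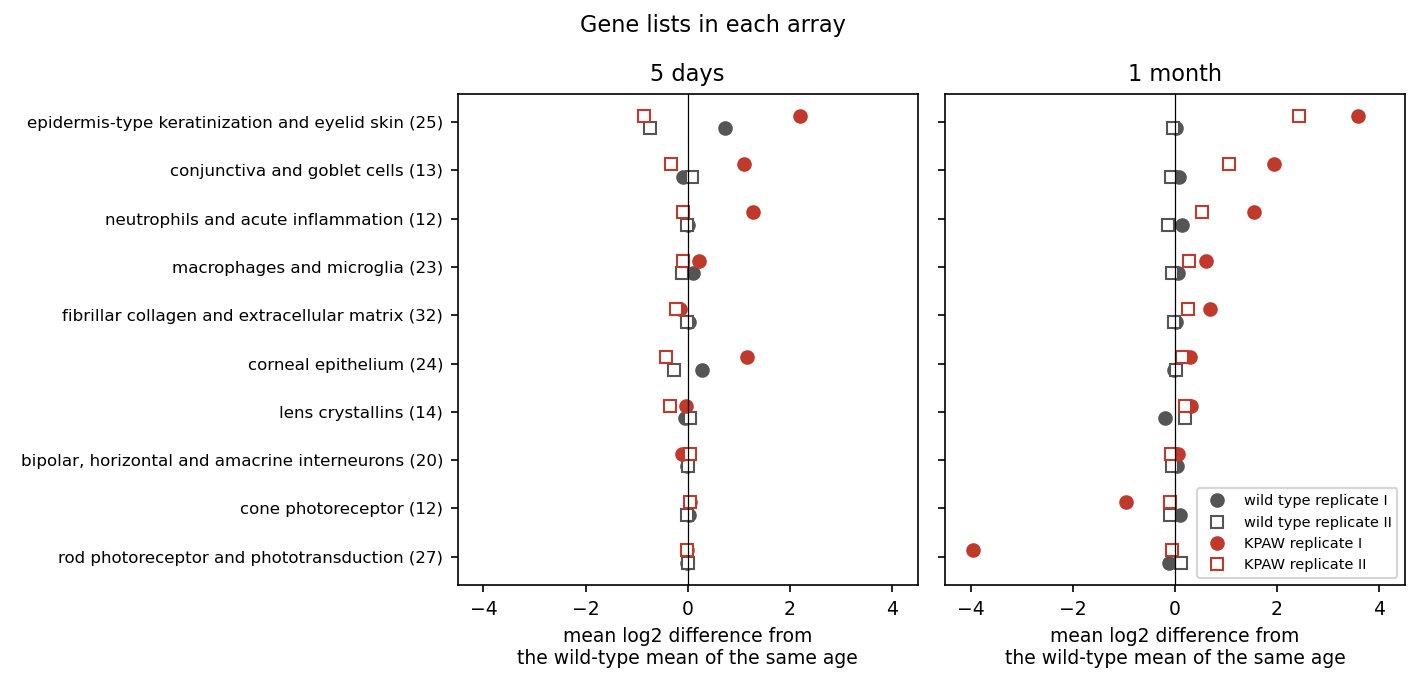
Mean log2 difference of 10 gene lists from the wild-type mean of the same age (x axis), by list with its number of genes (y axis), at 5 days (left) and 1 month (right); grey is wild type, red is KPAW, filled circles are replicate I and open squares replicate II. At 1 month the epidermis list lies at 3.59 and 2.43 in the KPAW arrays, and the rod list at -3.95 in replicate I and -0.06 in replicate II.

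The fibrillar collagen and extracellular matrix list lay higher at 1 month by a mean of 0.48 over 32 genes (adjusted p = 6.25e-15, and adjusted p = 0.548 with an estimated correlation), with 13 members higher adjusted over the list alone, among them Col1a1 (1.17, SE 0.24) and Col3a1 (1.13, SE 0.18), the main collagens of connective tissue. Macrophages and microglia lay higher by 0.45 over 23 genes (adjusted p = 3.19e-08, and adjusted p = 0.548 with an estimated correlation), with 5 higher adjusted over the list alone, among them Lyz1 (1.02, SE 0.28), Fcgr3 (0.95, SE 0.28) and the lysozyme Lyz2 (0.93, SE 0.19). Corneal stroma keratocytes and proteoglycans lay higher by 0.34 (17 genes, adjusted p = 4.51e-05, and adjusted p = 0.548 with an estimated correlation), with Bgn at 0.83 (SE 0.26) and Lum at 0.65 (SE 0.20), and none past the threshold either way. No member passed over all probe sets. All 3 kept their call without each of the 8 arrays, and in both KPAW arrays they lay above wild type, by more in KPAW I. In KPAW I and II in turn, collagen lay at 0.69 and 0.26, macrophages at 0.61 and 0.28, and corneal stroma at 0.55 and 0.14. Col1a1, Col3a1, Bgn and Lum passed over all probe sets without KPAW II at 1 month.

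Rod transcripts differed between the KPAW arrays at 1 month. The rod photoreceptor and phototransduction list lay lower by a mean of -2.0 over 27 genes (adjusted p = 1.46e-09, and adjusted p = 0.548 with an estimated correlation), at -3.95 in KPAW I and -0.06 in KPAW II. Its call was lost without KPAW I, where the mean was -0.05, list values from other fits being given relative to the median of all genes. The rod transducin Gnat1 read 0.0478 in KPAW I and 7.18 in KPAW II, against 6.0 and 7.09 in wild type. Nrl, the transcription factor that sets rod identity, was lower by -3.30 (SE 1.64) and Guca1b by -3.43 (SE 1.78). No member passed, over all probe sets or adjusted over the list alone, but Gnat1 (-6.57), Nrl (-6.57) and Guca1b (-6.92) did without KPAW II. Cone genes lay lower by -0.53 (12 genes, adjusted p = 0.00655, and adjusted p = 0.548 with an estimated correlation), at -0.95 in KPAW I and -0.10 in KPAW II, and lost their call without KPAW I (-0.10) or wild type I at 1 month. The cone opsin Opn1sw differed by -1.22 without passing (adjusted p = 0.675), and by -2.42 to -0.03 when an array was left out. The cone opsin Opn1mw was 0.463 ± 0.0863 in wild type and 0.514 ± 0.162 in KPAW (n = 2 each). Neutrophil and acute inflammation genes lay higher by 1.03 (12 genes, adjusted p = 0.0018, and adjusted p = 0.561 with an estimated correlation), by 1.54 in KPAW I and 0.52 in KPAW II, with S100a9 at 3.14 (SE 1.08) and S100a8 at 2.55 (SE 0.84). That call was lost without KPAW I (0.53).

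**Figure D2:**
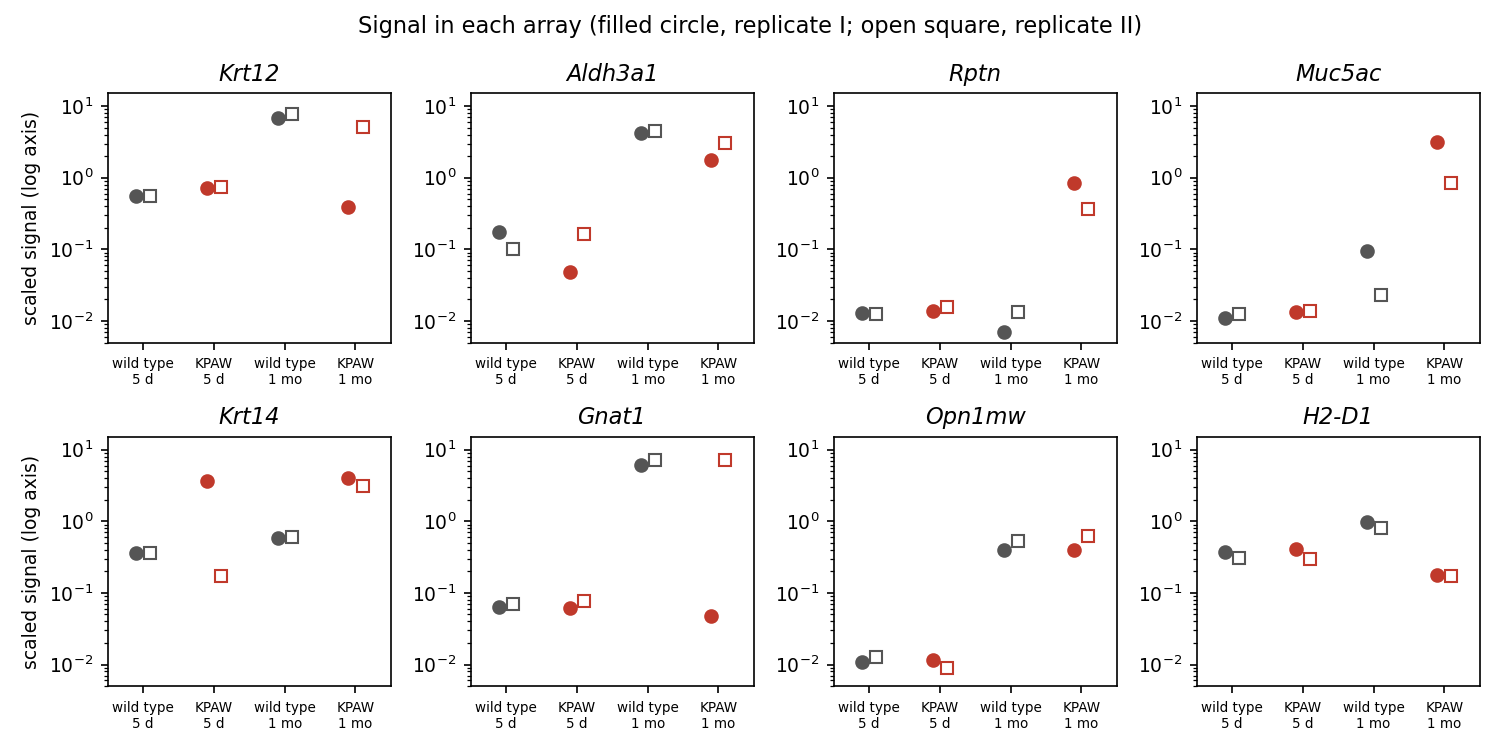
Scaled signal on a log axis for 8 genes, 1 panel each, in wild type (grey) and KPAW (red) at 5 days and 1 month, with filled circles for replicate I and open squares for replicate II. Gnat1 and Krt12 read 0.0478 and 0.391 in KPAW I at 1 month, against 7.18 and 5.13 in KPAW II, while Rptn lies above the wild-type arrays of that age in both.

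Of the 46 lists at 1 month, 23 passed by camera with the preset correlation, 19 higher and 4 lower, and none with an estimated correlation (lowest adjusted p = 0.548). The estimated correlation called no list in any contrast, so it does not separate these lists from unchanged ones. Of the 23, 5 kept their call without each array, the epidermis, collagen, macrophage, conjunctiva and corneal stroma lists. The other higher lists were cell cycle and proliferation (0.27, with the mitotic genes Birc5 at 0.81 and Mki67 at 0.62), basement membrane and lens capsule (0.27), lens membrane, cytoskeleton and regulators (0.32), lens crystallins (0.26), matrix proteases and inhibitors (0.32), melanocyte and pigment synthesis (0.22), complement (0.30), heat shock and unfolded protein response (0.17), Mueller glia and gliosis (0.31), ribosomal proteins (0.16), Wnt signalling (0.14), oxidative stress and detoxification (0.14), and fibrosis and epithelial to mesenchymal transition (0.17). Synapse and neurotransmission (-0.32) and retinal ganglion cells and axons (-0.14) were lower. Their members did not pass over all probe sets, and 1 basement membrane gene and 1 complement gene rose adjusted over the list alone; Birc5 passed without KPAW II. Fibrosis kept its call in 4 of 11 other settings, losing it with a replicate block and quantile normalization among others, and oxidative stress in 6 of 11. Ganglion cells lost theirs with a replicate block, and crystallins and ribosomal proteins with quantile normalization. As deposited, ganglion cells, ribosomal proteins, heat shock and Wnt signalling lost theirs. So did Wnt signalling, complement, cones and Mueller glia with a filter above the 50th percentile. Without KPAW I the cell cycle, basement membrane, protease, Mueller glia, ribosomal, Wnt, heat shock, oxidative stress, fibrosis and synapse lists lost their call. Without wild type I the crystallin, lens membrane, melanocyte, complement, Mueller glia, ribosomal, heat shock, oxidative stress, fibrosis, synapse and ganglion cell lists did so. Wnt signalling also lost it without wild type II, ganglion cells without wild type II or KPAW II, and fibrosis without either KPAW array of 5 days.

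At 5 days the same comparison asks which transcripts differ between KPAW and wild type in the early postnatal eye. No probe set passed in limma (lowest adjusted p = 1.00), and 377 had an unadjusted p under 0.05, where chance gives 792. A fit without a variance trend and a fit with array weights also called 0, with 397 and 629 at an unadjusted p under 0.05. The largest statistics among genes higher in KPAW, none of which passed, were those of Cap1, an actin-cycling protein gene (log2 fold change 0.90, SE 0.15), Aqp5 (1.28, SE 0.27), the retinol-binding protein gene Rbp2 (1.14), Kdf1 (0.88), Lin7b (0.89), Slc31a2 (0.84), Kat6a (0.47), Sidt2 (0.85), Entpd2 (0.69) and Slc30a5 (0.52). Among genes lower in KPAW they were those of the desaturase-family gene Fads3 (-1.06, SE 0.23), the RNA-editing enzyme Adarb1 (-0.72, SE 0.16), Atg13 (-0.72), Col5a1 (-0.62), Ide (-0.60), Ssna1 (-0.49), Pdlim4 (-0.72), Khdrbs1 (-0.59), Alox12e (-1.14) and Gcg (-0.92). Pax6 was 0.836 ± 0.194 in wild type and 0.975 ± 0.0572 in KPAW, and Krt12 0.550 ± 0.00372 and 0.731 ± 0.0140 (n = 2 each). Without KPAW II, whose sex markers match wild type, 27 probe sets passed, 26 higher and 1 lower. Xist was the lower one (-5.00), and Eif2s3y and Aqp5 were among the higher ones, so the calls then compare a KPAW array with male markers to wild-type arrays with female markers.

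At 5 days the fibrillar collagen list lay lower by a mean of -0.19 over 32 genes (adjusted p = 4.16e-05, and adjusted p = 0.856 with an estimated correlation), at -0.14 in KPAW I and -0.23 in KPAW II, with Col5a1 at -0.62 and Col6a3 at -0.56. The melanocyte and pigment synthesis list lay lower by -0.20 over 15 genes (adjusted p = 0.000166, and adjusted p = 0.811 with an estimated correlation), with the pigment-cell regulator Mitf at -0.46 and tyrosinase (Tyr), the rate-limiting enzyme of melanin synthesis, at -0.40. These were the 2 of 15 called lists that kept their call without each array. Lists lower by small means were retinal ganglion cells and axons (-0.22), oxidative phosphorylation (-0.15), lens membrane (-0.22), lens crystallins (-0.19), corneal stroma (-0.12), endothelium and angiogenesis (-0.16), basement membrane (-0.13), ribosomal proteins (-0.13) and ciliary body and iris (-0.15). No member of these lists passed, over all probe sets or adjusted over the list alone, and none of the 46 lists passed with an estimated correlation (lowest adjusted p = 0.811). Their calls were lost without KPAW I (ganglion cells, ciliary body), KPAW II (oxidative phosphorylation, crystallins, stroma, basement membrane, ribosomal proteins), wild type I (endothelium, ribosomal proteins) or wild type II (lens membrane, crystallins, basement membrane, ciliary body) of 5 days, and quantile normalization turned the signs of the crystallin (0.01) and ribosomal (0.0057) lists. Quantile normalization also ended the oxidative phosphorylation call, no filter the ciliary body call and a filter above the 50th percentile the endothelium call.

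Surface epithelium genes differed between arrays of the same group at 5 days, in KPAW and in wild type. In wild type I and II the epidermis list lay at 0.73 and -0.73 from their mean, and the corneal epithelium list at 0.27 and -0.27. The hair gene Krtap8-1 read 2.13 in wild type I and 0.417 in KPAW I, against 0.0477 in wild type II and 0.0513 in KPAW II. The epidermis list lay 2.20 above the wild-type mean in KPAW I and -0.85 from it in KPAW II (mean 0.67, adjusted p = 0.0186, and adjusted p = 0.904 with an estimated correlation), the corneal epithelium list at 1.16 and -0.43 (mean 0.37, adjusted p = 0.0316, and adjusted p = 0.904 with an estimated correlation), and the neutrophil list at 1.28 and -0.09 (mean 0.60, adjusted p = 0.00223, and adjusted p = 0.856 with an estimated correlation). KPAW I is the array with male markers. The keratin Krt14 read 3.69 in KPAW I and 0.169 in KPAW II, against 0.361 and 0.363 in wild type, and S100a9 differed by 2.06 (SE 1.08) without passing. Krt16 and Sprr1b were at the lowest listed value in both wild-type arrays and did not pass. Immediate early genes lay higher by 0.21 (adjusted p = 0.00257, and adjusted p = 0.811 with an estimated correlation), with Egr1 at 0.53 (SE 0.43). No member passed over all probe sets, and 1 corneal gene was higher adjusted over the list alone. Without KPAW I the epidermis, corneal and neutrophil lists changed sign (-0.85, -0.43 and -0.09), and the immediate early call was lost, while Krt14, Krt16 and Sprr1b passed without KPAW II. Without wild type II the epidermis list read -0.05, and the corneal and immediate early calls were lost. The corneal call was also lost without either wild-type array of 1 month or with no filter, and the epidermis call with no filter or with the groups of the contrast alone.

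The change in the KPAW difference from 5 days to 1 month was tested as an interaction. No probe set passed in limma (lowest adjusted p = 0.289), and 36 passed with the values as deposited. At an unadjusted p under 0.05 there were 933 probe sets, with 899 and no call in a fit without a variance trend, and 963 and no call with array weights. None of the largest statistics passed the threshold. The KPAW minus wild type difference was higher at 1 month than at 5 days for Rptn (4.11), Kdelr3 (1.40), Teddm3 (1.95), Tmem87a (1.52) and Cxcl17 (1.55). The Teddm3 and Cxcl17 values exceed their 1-month differences (1.93 and 1.35), so neither gene lay above wild type at 5 days. The difference was lower at 1 month for H2-D1 (-2.27), Egln3 (-1.14), Ppp1r3c (-1.28), Aqp5 (-2.03) and Ppil4 (-1.43). Without KPAW II at 1 month 306 probe sets passed, among them Rptn, Kdelr3, Teddm3, Cxcl17, H2-D1 and Ppil4. Without KPAW I or KPAW II at 5 days 1 and 11 passed, with the sex-linked Xist (5.12) and Eif2s3y beside Aqp5 and H2-D1 in the latter. By camera 24 of the 46 lists passed, 21 higher and 3 lower, and none with an estimated correlation (lowest adjusted p = 0.549). Of the 24, 12 kept their call without each array. The collagen list changed by 0.66 between the ages (adjusted p = 7.22e-17, and adjusted p = 0.549 with an estimated correlation), with 13 of 32 members passing adjusted over the list alone, and the epidermis list by 2.34 (adjusted p = 1.95e-06, and adjusted p = 0.549 with an estimated correlation), with 2 of 25. The rod list changed by -1.99 (adjusted p = 3.38e-06, and adjusted p = 0.549 with an estimated correlation), with no member passing. The epidermis call was lost without KPAW II at 5 days (0.81) and the rod call without KPAW I at 1 month (-0.05). Across 9492 genes the KPAW differences at the 2 ages correlated with a Pearson r of 0.041 and a Spearman rho of -0.083, genes not being independent replicates, and r was -0.257 without KPAW I at 5 days and 0.255 without KPAW II.

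From 5 days to 1 month the wild-type eye gained transcripts of the mature cornea and photoreceptors. Aqp5 rose from 0.0140 ± 0.00436 to 3.22 ± 0.0851 (n = 2 each, log2 fold change 6.54, SE 0.27, adjusted p = 7.43e-05), Aldh3a1 from 0.138 ± 0.0502 to 4.35 ± 0.291 (4.82, SE 0.45) and Slurp1 by 5.68 (SE 0.69). The mean Aqp5 signal at 5 days lay below the pseudocount of 0.0211, so the size of its rise depends on that setting. The rod transducin Gnat1 rose from 0.0667 ± 0.00469 to 6.55 ± 0.772 (6.22, SE 1.69, adjusted p = 0.0397). Other large rises were those of Kcnj14 (5.47), the rod cation exchanger Slc24a1 (4.64), the antibacterial protein gene Pglyrp1 (4.62), Plet1 (4.43) and Pdzph1 (4.35). Psca, at the lowest listed value in both arrays at 5 days, also rose. Fabp7, a fatty acid-binding protein of progenitors and glia, fell from 1.65 ± 0.0617 to 0.0226 ± 0.00629 (-5.26, SE 0.16, adjusted p = 1.73e-05). Xist (-5.24), the fetal growth factor Igf2 (-3.15), Dlk1 (-3.03), Capn3 (-2.97), Myb (-2.96), the lens gene Caprin2 (-2.86) and Nnat (-2.84) also fell, and the fall of Xist goes with the difference in sex markers between the ages. In wild type both arrays of 5 days had female markers and both of 1 month male ones. Age thus cannot be separated from sex for any wild-type call, nor from strain, which is given for the 5-day arrays alone. Mfap4 and Cpz fell to the lowest listed value in both arrays at 1 month. In all 2863 of 15838 probe sets passed, 1390 higher and 1473 lower, and 65.5% had groups that did not overlap, where chance gives 33.3%. Rises made up 48.6% of the calls, 37.6% with median scaling and 90.8% with the values as deposited, where the median of all probe sets shifted by 0.44 log2 units. The counts were 854 and 957 without wild type I or II at 5 days and 1100 and 1138 without wild type I or II at 1 month. Gnat1, Kcnj14, Slc24a1, Plet1, Pdzph1, Krt12 and Xist no longer passed without any 1 of these 4 arrays (highest adjusted p = 0.156 for Gnat1, which also lost its call without either KPAW array of 5 days).

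The lists that fell most with age in wild type, by camera with the preset correlation, were those of dividing cells, matrix and retinal progenitors. With an estimated correlation none of the 46 lists passed (lowest adjusted p = 0.401). The cell cycle list fell by a mean of 1.25 (27 of 34 genes fell, 32 adjusted over the list alone), among them Mki67 (-2.30), Cks2 (-2.09) and Cdk1 (-1.89), regulators or markers of mitosis. The fibrillar collagen list fell by 1.39 (25 of 32 fell; 26 fell and 1 rose adjusted over the list alone), with Col5a2 (-2.46), Col1a1 (-2.28) and Postn (-2.22). Retinal progenitors and neurogenesis fell by 1.34 (14 of 20 fell; 16 fell and 1 rose adjusted over the list alone), with Sox4 (-2.61), the Notch target Hes5 (-2.39) and Prdm1 (-1.89). Smaller falls were those of basement membrane (-0.62, 12 of 20), endothelium and angiogenesis (-0.56, 6 of 23 fell and 1 rose), lens membrane (-0.61, 4 of 12), eye field and neural crest transcription factors (-0.41, 5 of 18) and oxidative phosphorylation (-0.22, 6 of 25). Camera adjusted p for these lists ran from 9.53e-17 for the cell cycle to 0.0293 for oxidative phosphorylation, and with an estimated correlation from adjusted p = 0.401 to adjusted p = 0.702. Lens membrane lost its call without wild type I at 1 month, and oxidative phosphorylation without wild type I of either age, with quantile normalization and as deposited.

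Lists of mature tissue functions rose in wild type by camera with the preset correlation, and none of them passed with an estimated correlation (lowest adjusted p = 0.401). Corneal epithelium rose by a mean of 2.10 (13 of 24 genes, 16 adjusted over the list alone, adjusted p = 6.64e-08, and adjusted p = 0.497 with an estimated correlation) and the rod list by 2.38 (4 of 27, 10 adjusted over the list alone, adjusted p = 5.07e-05, and adjusted p = 0.702 with an estimated correlation). Cones rose by 1.67 (6 of 12, 8 adjusted over the list alone, adjusted p = 4.96e-06, and adjusted p = 0.401 with an estimated correlation), with the cone arrestin Arr3 at 3.14 and Opn1mw rising from the lowest listed value in both arrays at 5 days. Bipolar, horizontal and amacrine interneurons rose by 0.75 (6 of 20 rose and 1 fell; 10 and 3 adjusted over the list alone), with the bipolar genes Gng13 (3.58) and Pcp2 (3.57). Retinal pigment epithelium and visual cycle rose by 0.70 (5 of 16), with the isomerase Rpe65 at 3.66 and Rgr at 1.74. The circadian clock list rose by 1.01 (9 of 14, also adjusted over the list alone), with Dbp at 2.81 and Nr1d1 at 2.06, and the labels used here give no time of day. Interferon response and antigen presentation rose by 0.93 (13 of 24, 15 adjusted over the list alone), with the immunoproteasome subunit Psmb8 at 2.41. Glycolysis rose by 0.65 (12 of 20 rose and 1 fell), with Eno2 at 1.87. Oxidative stress and detoxification rose by 0.89 (10 of 24 rose and 1 fell), with Cbr2 at 3.69 and Gsta4 at 3.13. Synapse genes (0.66), cholesterol and lipid synthesis (0.36) and conjunctiva and goblet cells (1.34) rose too. The cholesterol call was lost without wild type II at 5 days (0.29) and the conjunctiva call without wild type I at 1 month (1.29).

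In KPAW eyes the same ages differed in 2261 probe sets, 1070 higher and 1191 lower, with 57.5% of probe sets not overlapping where chance gives 33.3%. Pglyrp1 rose from 0.0528 ± 0.0619 to 3.59 ± 1.47 (n = 2 each, log2 fold change 5.86, SE 0.56, adjusted p = 0.00109), Cbr2, a carbonyl reductase, from 0.0938 ± 0.0327 to 3.71 ± 0.445 (5.05, SE 0.22) and Muc5ac by 5.59 (SE 0.61). Cyp2f2 (4.89), Aqp5 (4.5), Aldh3a1 (4.38), Lce3c (4.29), Gp2 (4.09) and Sprr3 (4.09) also rose, as did the cone opsin Opn1mw from the lowest listed value in both arrays at 5 days. Fabp7 fell from 1.71 ± 0.248 to 0.0190 ± 0.00219 (-5.42, SE 0.16, adjusted p = 1.36e-05), and Insm1 (-3.24), Capn3 (-3.05), Igf2 (-2.94), Kcne1l (-2.90), Dlk1 (-2.81), the neuronal tubulin Tubb2b (-2.78), the developmental myosin Myh8 (-2.65), Sox4 (-2.62) and Myb (-2.57) fell. Krt12 differed by 0.96 (SE 0.92, adjusted p = 0.525), by 2.78 without KPAW I at 1 month and by -0.87 without KPAW II. Of the calls 47.3% were rises, 65.0% with the values as deposited, where 1343 passed, and the groups of the contrast alone gave 633. Without KPAW II at 5 days 734 probe sets passed, and KPAW I at 5 days, with the male markers of the 1-month arrays, was then the only KPAW array of that age.

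By camera with the preset correlation 24 of the 46 lists changed with age in KPAW, and none with an estimated correlation (lowest adjusted p = 0.385). The cell cycle list fell by 0.94 (22 of 34 genes, 27 adjusted over the list alone), progenitors by 1.29 (14 of 20; 17 fell and 1 rose adjusted over the list alone) and collagen by 0.73 (19 of 32 fell and 1 rose; 21 and 2 adjusted over the list alone), the interaction of the collagen list being the 0.66 given above. Corneal epithelium rose by 1.95 (10 of 24, 15 adjusted over the list alone), interferon response and antigen presentation by 0.93 (14 of 24 rose and 1 fell), with Psmb8 at 2.69, the clock list by 0.91 (9 of 14) and cones by 1.10 (5 of 12). Conjunctiva and goblet cells rose by 2.46 (6 of 13, 11 adjusted over the list alone) and the epidermis list by 2.11 (2 of 25, Lce3c and Sprr3). The epidermis mean in wild type was -0.23 (adjusted p = 0.844), and the interaction of that list was given above as 2.34. The rod list had a mean of 0.39 in KPAW with no member passing (adjusted p = 0.353), 2.35 without KPAW I at 1 month and -1.53 without KPAW II. Further lists that rose were oxidative stress (1.06), interneurons (0.78, with Gng13 at 3.88), pigment epithelium (0.65, with Rpe65 at 3.60), Mueller glia (0.65, with Aqp4 at 2.35), glycolysis (0.52), macrophages (0.48), ciliary body and iris (0.47), complement (0.44), heat shock (0.40), cholesterol synthesis (0.36), pericytes and smooth muscle (0.34), immediate early genes (0.46) and lens crystallins (0.19), and eye field factors (-0.39) and endothelium (-0.31) fell. The 24 calls included 13 that held without each array. Without KPAW I at 1 month the macrophage, ciliary, complement, heat shock, cholesterol, pericyte, immediate early and crystallin calls were lost. Without KPAW II at 5 days the calls were lost for the epidermis (0.61), pericytes, immediate early genes, crystallins, eye field factors and endothelium. The eye field call was also lost without KPAW II at 1 month, the endothelium call without that array or KPAW I at 5 days, and the immediate early call without either wild-type array of 1 month. Quantile normalization turned the crystallin list to -0.09. In other settings pericytes kept their call in 6 of 11, immediate early genes in 7, and crystallins and endothelium in 9 each.

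**Figure D3:**
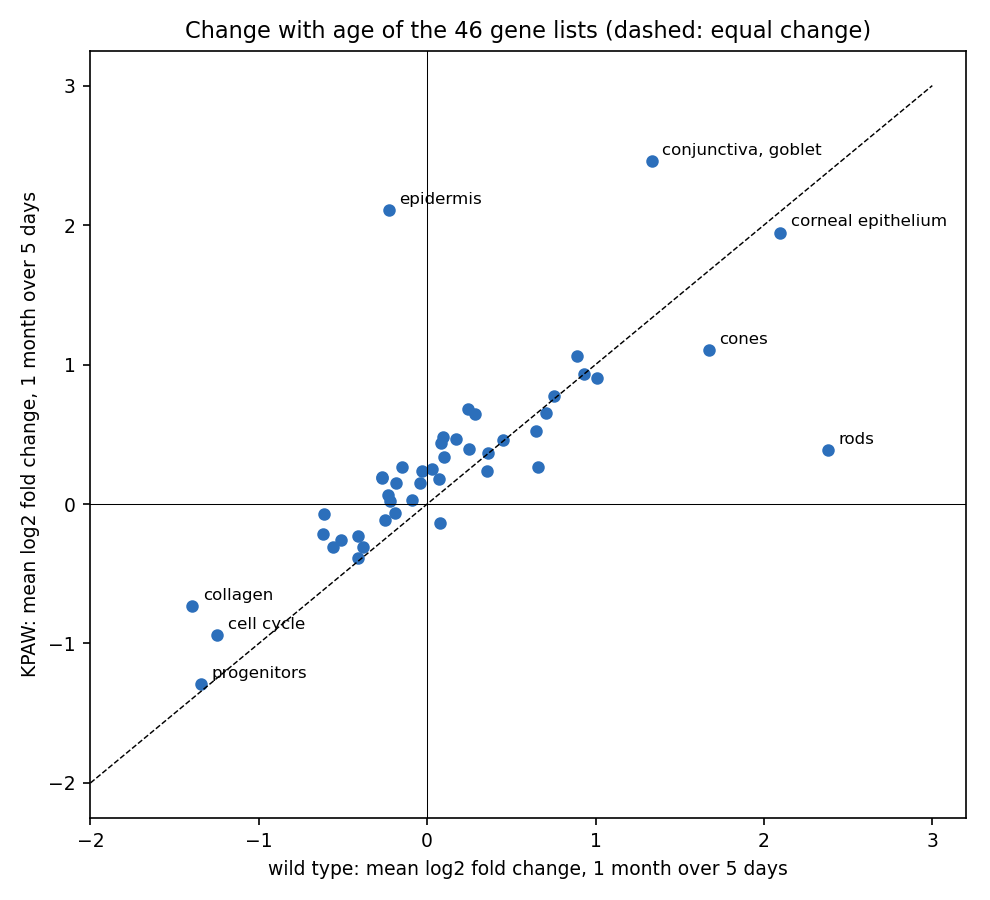
Mean log2 fold change of each of the 46 gene lists from 5 days to 1 month in wild type (x axis) and in KPAW (y axis), 1 point per list, with a dashed line of equal change. Cell cycle, progenitor and collagen lists fell in both, the epidermis list lies at -0.23 in wild type and 2.11 in KPAW, and the rod list at 2.38 and 0.39.

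Across 9492 genes the age changes in wild type and KPAW correlated with a Pearson r of 0.764 and a Spearman rho of 0.726, genes not being independent replicates. Of the probe sets called in both, 737 rose in both, where chance gives 93.9, 787 fell in both, where chance gives 111, and 3 moved in opposite directions.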

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

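Of the tests in this part, those of hair-bearing skin and of a strain difference over large stretches of the genome were written before their results were seen, and all the others were chosen only after the result was seen.

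Rod transcripts stood far below wild type in KPAW I at 1 month, while the rod list of KPAW II lay at -0.0583 (SD 0.19). Less retina in the sample is argued against by the interneuron list, which lay 0.0567 from wild type in KPAW I (SD 0.39 over genes). A mislabelled eye of a 5-day-old animal is argued against by the 1473 probe sets that fell with age in wild type, whose median position was 0.25 between 1-month (0) and 5-day (1) wild type (quartiles 0.0165 and 0.469, and 0.0765 in KPAW II), and degraded RNA by a 3' to 5' Gapdh ratio of 0.808, within the 0.799 to 0.959 of the other arrays. A variant carried by 1 animal that affects rods may account for it and cannot be told apart from other events in that eye: H2-D1 differed by only 0.0285 between the KPAW arrays, which speaks to that region of the genome alone. The rod gene Pde6b, picked after its values were seen, read 0.0105, the lowest listed value, in KPAW I and 2.33 in KPAW II. At 5 days Pde6b read 0.108 in KPAW II, against 0.404 in KPAW I and 0.297 and 0.327 in wild type. The rod list of KPAW II at 5 days lay at -0.0085. An effect of KPAW that appears in some eyes was not tested and stays open.

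Epidermal transcripts were high in both KPAW arrays at 1 month. Hair-bearing skin in the sample is argued against by 35 hair follicle genes, whose mean lay at most 0.0822 above wild type in either KPAW array (SD 0.226 over genes). Wild type I at 5 days read 2.13 for Krtap8-1, 1.26 for Krt71 and 0.717 for Tchh. The list can thus register hair, though it covers growing hair only. Sex of the animals is argued against by male markers in all 4 arrays of that age. Some corneal genes were low, such as Krt12 at 0.391 in KPAW I against 6.77 and 7.82 in wild type. Dilution of the whole eye to that extent would lower lens and retina too. It is argued against by lens crystallins, at 0.321 (SD 0.14) in KPAW I and 0.197 (SD 0.0968) in KPAW II. Interneurons lay at 0.0567 (SD 0.39) and -0.0744 (SD 0.238). Some retinal lists were lower in KPAW I, rods most, at -3.95. A smaller share of corneal epithelium alone stays open. The 24 genes of that list went both ways, with a mean of 0.30 in KPAW I and 0.133 in KPAW II (SD 1.69 and 0.823). Conjunctiva or lid margin in the sample cannot be told apart from a change of the ocular surface in KPAW, which stays a hypothesis: the goblet cell list lay at least 1.07 above wild type in both KPAW arrays and the gland list 0.49 and 0.24, which either could give.

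Class I histocompatibility probe sets at 1 month moved apart in KPAW: of 8 probe sets of H2-D1 and H2-K1, 5 were lower by over 1 log2 unit and 1 was higher. Allele differences under the probes could give opposite directions, but the same 5 probe sets differed at 5 days by a mean of only 0.06 (-0.07 to 0.20), where an allele carried by KPAW at both ages would show too. Lower expression of class I molecules at 1 month and an allele carried by the animals of that age alone cannot be told apart here. The partner genes B2m, Tap1, Tap2, Psmb8 and Psmb9, with a mean of 0.145 (SD 0.17), need not fall with H2-D1 and H2-K1. A second B2m probe set, outside that mean, was higher by 0.75 (SE 0.15) without passing. Lower expression alone does not account for the H2-D1 probe set that was higher by 2.33 (SE 0.55). That is 1 probe set, and it did not pass. A strain difference over large stretches of the genome was tested by the positions of the 100 genes with the most negative moderated statistics. Only genes lower in KPAW thus entered, and 1 such gene had passed, so most of the 100 had not. The 100 genes made 8 neighbouring pairs where 1000 random draws made 9.86 on average (permutation p = 0.803), so these genes were not clustered. A background that differs throughout the genome need not give neighbouring pairs, so the test cannot decide. The labels give a strain for the 5-day wild type alone, so a difference in background, in this region or more widely, stays open.

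The difference between KPAW and wild type changed from 5 days to 1 month in 24 of the 46 lists by an interaction test with the preset correlation, and in none with an estimated correlation (lowest adjusted p = 0.549). With the preset correlation it changed by 2.34 log2 units for epidermis-type keratinization, 1.12 for conjunctiva and goblet cells, 0.66 for fibrillar collagen, 0.54 for lens membrane, 0.47 for corneal stroma, 0.45 for lens crystallins, 0.42 for melanocytes, 0.41 for basement membrane and 0.39 for macrophages. The change was 0.36 for Mueller glia, 0.35 for complement, 0.33 for adipocytes, 0.30 for the cell cycle, 0.30 for ciliary body and iris, 0.29 for ribosomal proteins, 0.27 for matrix proteases, 0.25 for endothelium, 0.24 for pericytes, 0.24 for oxidative phosphorylation, 0.23 for Wnt signalling and 0.19 for fibrosis. It was -0.39 for synapse genes, -0.57 for cones and -1.99 for rods. Without KPAW I at 1 month the call was lost for rods (-0.05), cones, synapse genes, Mueller glia, endothelium, Wnt signalling, proteases, fibrosis, pericytes and adipocytes, and without KPAW II at 5 days for epidermis (0.81), conjunctiva (0.41), synapse genes, proteases, fibrosis and pericytes. Without wild type I at 5 days it was lost for endothelium, synapse genes, proteases, fibrosis, pericytes and adipocytes (-0.23), and without wild type I at 1 month for cones, synapse genes, fibrosis, pericytes and adipocytes. Proteases, pericytes, adipocytes and Wnt signalling lost it without wild type II at 1 month, fibrosis and pericytes without wild type II at 5 days, pericytes and adipocytes without KPAW II at 1 month, and adipocytes without KPAW I at 5 days. Adipocytes thus kept it in 2 of 8 such fits, pericytes in 1 and fibrosis in 3, and pericytes and fibrosis also lost it with a replicate block. Other settings ended it for adipocytes (3 of 10), pericytes (4), fibrosis (4), oxidative phosphorylation (2), ribosomal proteins, crystallins, cones and proteases (1 each).

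An 18S ribosomal RNA control probe set, not used in the comparisons, read 3.38 in KPAW I and 1.43 in KPAW II at 1 month, above the 0.973 and 0.857 of wild type I and II. At 5 days it read 0.781 and 1.82 in wild type and 2.29 and 0.498 in KPAW.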

How the results depend on the processing

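Among these tests the values as deposited, a common floor and array weights were chosen after seeing the data. Of the gene results under all alternatives 4613 kept their direction and side of the threshold, 127 became stronger, 92 weaker and 2 turned; of the list results, given relative to the median of all genes, 4045, 95, 168 and 16. Of the counts 79 stayed within 1.5 times. For KPAW against wild type at 1 month the 4 calls became 2 with a pseudocount at the 5th percentile, 2 with a filter above the 50th percentile, 19 with the groups of the contrast alone, 13 with a replicate block, 99 as deposited and 1 with array weights. The interaction had 36 as deposited. Age in wild type gave 1860 with 1 probe set per gene and 1274 at 2-fold or more, and age in KPAW 1494 and 1027, with 633 from its groups alone and 1343 as deposited. With a replicate block the other counts were 0 for KPAW at 5 days, 0 for the interaction, 2991 for age in wild type and 2367 for age in KPAW. The values as deposited shift the median of all probe sets by 0.18 for KPAW at 5 days, -0.26 at 1 month, -0.45 for the interaction and 0.44 for age in wild type. They also turned Cryaa with age in wild type to 0.50. Quantile normalization turned lens crystallins (0.0107) and ribosomal proteins (0.0057) for KPAW at 5 days, and lens crystallins with age in KPAW (-0.0930). Leaving out each array in turn gave 0 to 27 calls for KPAW at 5 days, 0 to 563 at 1 month, 0 to 306 for the interaction, 854 to 3687 for age in wild type and 734 to 2174 for age in KPAW, and a correlation between the KPAW differences of -0.257 to 0.255. Lists that turned when an array was left out ranged, for KPAW at 5 days, from -0.43 to 1.18 for corneal epithelium, -0.85 to 2.21 for epidermis (also -0.05), -0.33 to 1.11 for conjunctiva, -0.40 to 0.19 for muscle, -0.29 to 0.79 for glands, -0.66 to 0.47 for adipocytes and -0.0863 to 1.30 for neutrophils. Muscle at 1 month ranged from -0.25 to 0.24. For the interaction the ranges were -0.95 to 0.65 for corneal epithelium, -0.23 to 0.91 for adipocytes and -0.18 to 0.20 for immediate early genes. With age in KPAW rods ranged from -1.53 to 2.35 and Krt12 from -0.87 to 2.78. Fewer probe sets enter with 1 probe set per gene or a filter above the 50th percentile, fewer arrays with the groups of the contrast alone or an array left out, and a 2-fold minimum changes the call rule alone; beyond that the cause was not tested. A lone array left in a group is assumed to vary like the other groups.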

Other observations

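Of the tests in this part, the correlation of replicate deviations was chosen only after the data were seen; the list tests were fixed in advance.

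The following lists of eye tissues did not pass between KPAW and wild type at 1 month. The interneuron list of the inner retina had a mean of -0.01 over 20 genes (adjusted p = 0.964), and eye field and neural crest transcription factors 0.01 (adjusted p = 0.782). Retinal pigment epithelium and visual cycle had -0.14 (adjusted p = 0.41) and retinal progenitors 0.14 (adjusted p = 0.773), with a mean and a median of opposite sign and 1 gene higher adjusted over the list alone. Ciliary body and iris had 0.15 (adjusted p = 0.0526). Lacrimal, Harderian and meibomian glands had 0.37 over 10 genes (adjusted p = 0.0835), with 2 higher adjusted over the list alone. Tissue around the eye gave 0.23 for adipocytes (adjusted p = 0.175), -0.09 for Schwann cells and myelin (adjusted p = 0.821), 0.20 for red blood cells (adjusted p = 0.747), 0.09 for endothelium (adjusted p = 0.212), 0.12 for pericytes and smooth muscle (adjusted p = 0.172) and 0.09 for T, B and mast cells (adjusted p = 0.737). Extraocular and skeletal muscle had a mean just below 0 with a median of 0.07 (adjusted p = 0.903) and 1 gene lower adjusted over the list alone. The gland list passed with the groups of the contrast alone, as deposited (0.40), and without any 1 of the 4 arrays of 5 days (0.37). Adipocytes passed with the groups alone and without either wild-type array of 5 days (0.23). Ciliary body and iris passed with a pseudocount at the 40th percentile (0.13) and without KPAW II at 1 month (0.24), endothelium with a filter above the 50th percentile (0.17) and without KPAW II (0.20), and muscle without KPAW I (-0.25).

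Among lists of cell programs, these did not pass at 1 month. Interferon response and antigen presentation had a mean of 0.03 (adjusted p = 0.246). Its H2-D1 probe set passed as lower when adjusted over all probe sets tested, while another H2-D1 probe set was higher by 2.33 without passing. Adjusted over the list alone, 1 gene was higher and 2 lower. The means were 0.15 for cell death and p53 (adjusted p = 0.14), 0.22 for immediate early genes (adjusted p = 0.0905), 0.10 for BMP and TGF-beta signalling (adjusted p = 0.127), 0.09 for oxidative phosphorylation (adjusted p = 0.09), -0.13 for glycolysis (adjusted p = 0.215), -0.11 for the circadian clock (adjusted p = 0.548) and -0.09 for sex-linked genes (adjusted p = 0.823). Cholesterol and lipid synthesis had 0.01, with a median and a test of the other sign (adjusted p = 0.902). Immediate early genes passed with the groups of the contrast alone, as deposited, and without KPAW I or KPAW II at 5 days (0.22) or wild type II at 1 month (0.30). Without KPAW II at 1 month cell death (0.28), BMP signalling (0.22) and glycolysis (-0.29) passed, without wild type II cell death (0.24) and oxidative phosphorylation (0.16), and without wild type I interferon response (0.23). Cell death also passed with no filter (0.18) and glycolysis with quantile normalization (-0.18).

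Within the wild-type eye, lists that did not pass with age held members moving both ways. In retinal ganglion cells and axons (-0.38, adjusted p = 0.0701) 1 gene rose and 3 fell, with the growth-associated genes Stmn2 (-1.82) and Gap43 (-1.71) lower and the mature neurofilament Nefh (1.32) higher. Of 22 Mueller glia genes 8 rose and 2 fell (0.28, adjusted p = 0.0791), and of 17 corneal stroma genes 2 rose and 7 fell (-0.27, adjusted p = 0.201).

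Replicates with the same numeral deviated from their group means together to a small extent. The deviations correlated across probe sets at 0.309 between wild type and KPAW at 5 days, 0.199 between KPAW at the 2 ages and 0.126 between wild type at 5 days and KPAW at 1 month. The other pairs, each with wild type at 1 month, gave -0.0136, -0.0173 and 0.0160. Probe sets are not independent replicates, and the labels do not say whether a numeral marks a shared batch.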
